A study of Mus musculus with 12 samples.

How the data were processed

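Messenger RNA was profiled in 12 libraries of total CD4+ T cells from mouse spleen, 3 in each of 4 groups: ethanol vehicle or cyclosporin A (CsA), each left unstimulated or stimulated with phorbol 12-myristate 13-acetate (PMA) plus ionomycin. Per the submitters' processing notes, reads were trimmed with cutadapt and quantified with kallisto against mm10; the versions and the transcript annotation were not given. The deposited tables hold the estimated count of each transcript, which the authors' kallisto run left unscaled for depth. Per the file headers they also hold TPM (transcript abundance scaled for length and depth within each sample). Transcript length and effective length in bases, per the file headers, were read as well, and the effective lengths were identical in all 12 deposited tables. Of the transcripts listed, 108214 of 109617 were matched by identifier to mouse annotation on the build mm10, and 92.5% of these had the length that the annotation gives. The 1403 unmatched transcripts carried between 0.494% and 0.629% of the counts of a library and were left out of gene sums.

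Estimated counts were summed over the transcripts of a gene and rounded to whole numbers. Main tests were run in R 4.3.3 with edgeR 4.0.16: TMM scaling, the edgeR expression filter by group (minimum count 10, minimum total 15), and quasi-likelihood fits with robust estimation. All 4 groups entered 1 fit, so that the comparisons shared an estimate of the spread. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The 5 comparisons were stimulation in vehicle-treated cells, CsA in stimulated cells, CsA in unstimulated cells, stimulation in CsA-treated cells, and the interaction, which is the stimulation effect under CsA minus that in vehicle. Fold changes are log2 values. Their standard error (SE) was derived as the absolute log2 fold change divided by the square root of the F statistic of its test. Levels are TMM-scaled CPM (counts scaled to library size) with the standard deviation (SD) over 3 libraries. Where a group had no count of a gene, the fold was bounded against a floor of 3 counts over that group.

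Before the data were examined, 25 gene lists, the named genes, the tests and most alternatives were fixed. The lists covered cytokines and secreted effectors, chemokines, TNF-family ligands, the AP-1 family, other immediate-early genes, the calcineurin-NFAT pathway, cyclophilins, NF-kB pathway and feedback, activation surface markers, inhibitory receptors and anergy genes, quiescence and homing, T helper lineage transcription factors, ribosome biogenesis, glycolysis and glucose uptake, amino acid transport and ATF4 targets, heat shock and chaperones, interferon-stimulated genes, T cell identity, regulatory T cell markers, B cell markers, CD8 and NK markers, myeloid and dendritic markers, erythroid and platelet markers, mitochondrial transcripts, and housekeeping genes. Of their 367 symbols, Batf3, Rcan2 and Il9 did not pass the filter with all 12 libraries. Lists were tested with camera (limma 3.58.1, preset correlation 0.01), with camera at an estimated correlation, and with fry, each adjusted over the 25 lists within a comparison. Members were also counted with p-values adjusted over the list alone.

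The rule for named genes had 4 parts. It took 15 fixed genes; per comparison the 8 largest rises and 8 largest falls among called genes with a mean of at least 10 CPM and no overlap between the groups, or 3 and 3 in the smaller comparisons; list members as examples; and the 6 most induced genes with no call for CsA in stimulated cells or in the interaction. The rule also asked for the 6 largest rises with CsA among induced genes. Genes outside the rule are named as chosen after their values were seen. Induced genes were those called with at least a 2-fold rise in vehicle. Because that rise and the effect of CsA share the vehicle-stimulated libraries, their covariance was also simulated from counts with the observed stimulation and no CsA effect, and correlations from counts with neither effect. Transcripts of Nfatc1, Rcan1, Crem and Homer1 were tested by the same edgeR method on transcript counts, adjusted over these transcripts.

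The replicate numbers of the labels were examined as pairs by correlating, across genes, the deviations of equally numbered libraries from their group means. These correlations were 0.143 to 0.319 between the vehicle groups, 0.196 to 0.325 between the unstimulated groups and 0.107 to 0.208 between the stimulated groups, where the values without the library labelled CsA_PI 2 were 0.121 and 0.044. The pairing comes from the labels' numbers alone, which do not say what they share, and the main tests were unpaired with the number as an alternative block. The library labelled CsA_PI 2 was kept under its label. It was doubted after its values were seen, so each count that involves it was computed again from the other 11 libraries.

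Other alternatives were RLE scaling, library totals, no low-count filter, a filter of 5 CPM in 3 libraries, DESeq2 1.42.0, a fit of only the groups compared, counts rescaled from TPM by length, induction of at least 4-fold, and each library left out in turn. Added after the data were seen were removal of ribosomal-RNA-like features, omission of all libraries numbered 2, and the block, DESeq2, RLE and library totals each without the library labelled CsA_PI 2. The method was tested on simulated data with changes of known size. No deposited sample column was left unused (0 columns). Tables were read with Python 3.11.15 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.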

Results

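RNA sequencing covered total CD4+ T cells of C57BL/6 spleens, purified by removal of other cells. Cells received 1 µM CsA or its ethanol vehicle for 1 h and were then left unstimulated or given 10 nM PMA with 1 µM ionomycin for 2 h. PMA activates protein kinase C and ionomycin raises calcium, so together they bypass the T cell receptor. CsA binds cyclophilins, and the complex blocks calcineurin, the phosphatase that lets NFAT transcription factors enter the nucleus. SMART-seq, the library method, copies polyadenylated RNA into full-length cDNA and amplifies it by PCR. Each of the 4 groups had 3 libraries. Vehicle unstimulated libraries held 14733434, 15197221 and 14674704 estimated counts, CsA unstimulated 18468044, 14497614 and 11441312, vehicle stimulated 11514758, 13111910 and 10523816, and CsA stimulated 14564964, 12958689 and 11288315. A count of 0 allowed a level of up to 0.162 to 0.285 CPM, depending on the library. The labels do not say that the replicates were separate animals, so p-values measure the spread between these libraries, which may be technical. Reads carried no molecular identifiers, and the floors for a count of 0 cover counting error only.

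The library labelled CsA_PI 2 stood apart from the other CsA-stimulated libraries. Il2 was at 2.59 CPM in it, against 25.4 and 23.3 CPM in CsA_PI 1 and 3. Egr1, an immediate-early transcription factor, was at 62.2 CPM in it, against 1063 and 1202 CPM. S1pr1, the receptor that draws lymphocytes out of lymphoid organs, was at 481 CPM in it, against 317.5 and 314 CPM. Over the genes induced in vehicle, its mean log2 CPM was 4.23, beside 4.04 to 4.20 in the unstimulated libraries; CsA_PI 1 and 3 stood at 5.06 and 5.09 and the vehicle-stimulated libraries at 6.15 to 6.19. Counts of called genes that rest on the CsA-stimulated group are therefore given from all 12 libraries and again from the 11 others, and list counts from all 12 unless stated, a choice made after the data were seen.

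**Figure D1:**
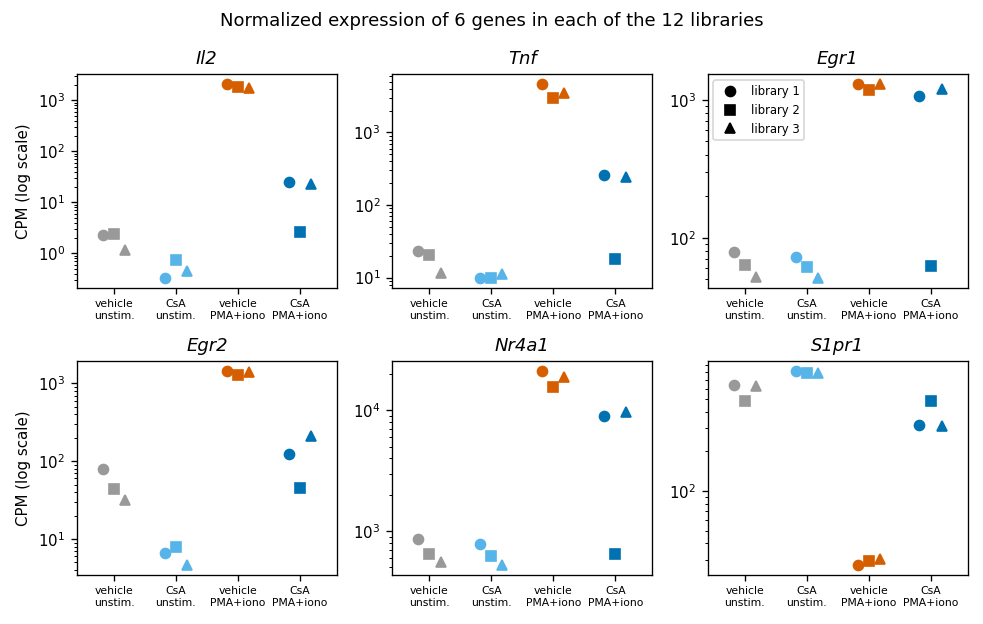
Level of 6 genes in each library, in TMM-scaled CPM on a log axis, with one marker shape per replicate number and one colour per group. CsA_PI 2, the square in the last column of each panel, lies near the unstimulated libraries for Egr1 (62.2 CPM) and Nr4a1 (651 CPM).

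Stimulation of vehicle-treated cells gave the full response against which CsA was set. Il2, the T cell growth factor, rose from 1.95 ± 0.682 to 1885 ± 169.9 CPM (mean ± SD, n = 3), a log2 fold change of 9.91 ± 0.84 (SE; edgeR adjusted p = 1.25e-05). Tnf, an inflammatory cytokine, rose from 18.2 ± 6.03 to 3693 ± 868 CPM (7.66 ± 0.90; adjusted p = 0.000102). Ifng, which encodes interferon gamma, rose by 6.94 ± 0.65 (adjusted p = 1.81e-05) and Csf2, a myeloid growth factor, by 7.70 ± 0.99. S1pr1 fell from 584 ± 85.4 to 29.2 ± 1.54 CPM (−4.32 ± 0.22; adjusted p = 6.95e-07). On the mouse build mm10, Il2 (ENSMUSG00000027720) lies on chromosome 3 from 37120523 to 37125959, Tnf (ENSMUSG00000024401) on chromosome 17 from 35199381 to 35202007 and Ifng (ENSMUSG00000055170) on chromosome 10 from 118441046 to 118445892. Egr1 (ENSMUSG00000038418) lies on chromosome 18 from 34859823 to 34864984, Nfatc1 (ENSMUSG00000033016) on the same chromosome from 80606205 to 80713071, and S1pr1 (ENSMUSG00000045092) on chromosome 3 from 115710433 to 115715072.

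Transcription factors and surface receptors of early activation rose with the cytokines. Egr1 rose by 4.29 ± 0.81, its relative Egr2 by 4.73 ± 0.54, the orphan nuclear receptor Nr4a1 by 4.77 ± 0.77 and the growth regulator Myc by 5.64 ± 0.69. The AP-1 subunits Fos and Jun rose by 2.67 ± 0.44 and 1.40 ± 0.24. Cd69, an early activation marker that retains cells in tissue, rose by 4.14 ± 0.54, and Il2ra, the high-affinity chain of the Il2 receptor, by 4.11 ± 0.82. Nfatc1, the inducible NFAT, rose by 2.33 ± 0.17, the NF-kB inhibitor Nfkbia by 2.13 ± 0.23 and the calcineurin regulator Rcan1 by 1.63 ± 0.49. The largest rises by the naming rule also held Il13 (9.48 ± 1.27), Ccl4 (8.77 ± 1.18) and Ccl3 (8.41 ± 1.01). Il17a and Ccl1 belonged to them too, at 111 and 42.5 CPM in stimulated against 0.0197 and 0.0391 CPM in unstimulated cells, too few counts for a fold. Il3 had no count in unstimulated cells and was higher by at least 7.13 on the log2 scale. Large falls included those of Rflnb (−5.64 ± 1.30), Tbxa2r (−5.26 ± 1.03), Tdrp (−5.08 ± 0.73), Tmie (−4.90 ± 0.94), Bambi-ps1 (−4.36), S1pr1 and Card6 (−4.08 ± 0.50).

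By list, 18 of 20 measured cytokines rose and none of them fell (median 6.78; camera adjusted p = 1.42e-13), as did 5 of 6 chemokines (adjusted p = 3.89e-06, or adjusted p = 0.0955 with an estimated correlation) and 7 of 8 TNF-family ligands (adjusted p = 1.25e-10), among them Tnfsf14 (5.66), a costimulatory ligand. Of the AP-1 family 11 of 12 rose, or 12 adjusted over the list alone, with Fosl1 at 6.19 and Atf3 at 4.63; Jund, at 1.53 (adjusted p = 0.0531), was called with the replicate number as a block (1.47). Other immediate-early genes counted 20 higher and 1 lower of 24. NF-kB pathway genes counted 17 higher and 2 lower of 21, with Nfkbid at 5.90 and Rel at 3.39. All 24 ribosome biogenesis genes rose (median 2.80; adjusted p = 4.7e-34), including Nolc1 (3.81) and the RNA polymerase I subunit Polr1b (3.75). Glycolysis counted 11 higher of 18, with hexokinase Hk2 at 3.68, amino acid transport 9 higher and 1 lower of 15, and heat shock genes 8 higher of 12. Surface activation markers counted 9 higher of 12, and inhibitory receptors 13 higher and 1 lower of 19, with Cd160 at 5.02 and Btla at 3.55. T helper transcription factors counted 8 higher and 2 lower of 18, with Irf4 at 5.17 and Tbx21 at 3.98. T cell identity genes counted 9 higher and 3 lower of 14 and regulatory T cell markers 5 higher of 10.

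Quiescence and homing genes moved the other way, with 12 lower and 2 higher of 20 (median −1.45; camera adjusted p = 7.13e-06); Txnip was at −3.98 and Il7r, the receptor for the survival cytokine interleukin 7, at −3.24. Interferon-stimulated genes split, with 3 higher and 5 lower of 15 and Ifit2 at −2.81 (adjusted p = 0.671). The calcineurin-NFAT pathway split as well, with 6 higher and 4 lower of 20, Orai1 at 2.57 and Rcan3 at −2.84 (adjusted p = 0.712). Cyclophilins counted 4 higher of 7 (adjusted p = 0.0225, or 0.249 with an estimated correlation), led by Ppif at 2.07, and housekeeping genes 4 higher and 1 lower of 12 (adjusted p = 0.212).

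In all, 5728 of 14398 genes were called, 2892 higher and 2836 lower. With an estimated correlation, 7 list calls held at an adjusted p of 0.0356 (cytokines, TNF-family ligands, inhibitory receptors, quiescence, ribosome biogenesis, glycolysis and amino acid transport). Adjusted p was 0.0955 with an estimated correlation for chemokines and immediate-early genes, 0.118 for NF-kB, 0.122 for activation markers, 0.127 for heat shock, 0.137 for AP-1, 0.173 for T helper factors, 0.209 for T cell identity and 0.0994 for regulatory T cell markers. Without CsA_PI 2, which enters the shared spread, these values were 0.00181 for immediate-early genes, AP-1 and activation markers, 0.01 for NF-kB, 0.0214 for chemokines and 0.0465 for heat shock, while T helper factors, T cell identity and regulatory T cell markers stayed uncalled (0.0774, 0.213 and 0.0774). By fry with all 12 libraries, the adjusted p of each of these lists was at most 0.000861. Scaling by library totals moved the median of all genes by −0.60 and the split of calls to 1580 higher and 5437 lower. Under that scaling the housekeeping list turned (1 higher, 3 lower; median −0.20) and the calcineurin-NFAT list went to 2 higher and 11 lower.

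CsA in stimulated cells was the comparison named by the design text, and asked which part of the response was sensitive to CsA. Il2 fell from 1885 ± 169.9 CPM to 25.4, 2.59 and 23.3 CPM in the CsA libraries, a log2 fold change of −6.79 ± 0.73 (SE; edgeR adjusted p = 9.39e-05). Ifng fell to 52.2 ± 36.5 CPM (−5.00 ± 0.60; adjusted p = 0.000165) and Tnf to 257, 18.0 and 245 CPM (−4.41 ± 0.78; adjusted p = 0.00229). Without CsA_PI 2 the falls of Il2, Ifng and Tnf were −6.23 ± 0.30, −4.49 ± 0.35 and −3.84 ± 0.30. Nfatc1 fell by 2.30 ± 0.17 on the log2 scale (adjusted p = 5.02e-06), with 193, 222 and 230.3 CPM in the CsA libraries against 210.2 ± 15.2 CPM in unstimulated vehicle cells. Egr1 was not called, at −0.70 ± 0.71 (adjusted p = 0.541), and at −0.12 ± 0.19 (adjusted p = 0.725) without CsA_PI 2.

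Further falls were seen in Csf2 (−4.59 ± 0.82, or −3.99 without CsA_PI 2), Egr2 (−3.46 ± 0.51), Myc (−2.90 ± 0.61), Cd69 (−2.07 ± 0.49), Nfkbia (−1.80 ± 0.22) and Rcan1 (−2.38 ± 0.50, or −3.41 ± 0.37 without CsA_PI 2). Jun, at −0.74 ± 0.23 (adjusted p = 0.0377), lost its call without CsA_PI 2 (−0.52; adjusted p = 0.111) and with the replicate number as a block (−0.73). Fos stood at −0.80 ± 0.41 (adjusted p = 0.194) and Il2ra at −0.81 ± 0.73 (adjusted p = 0.48). Nr4a1, at −1.53 ± 0.68 (adjusted p = 0.133), was called lower without CsA_PI 2 (−0.96 ± 0.23; adjusted p = 0.00956). The helper cytokines Il21 (−7.08 ± 0.57, or −7.85 without CsA_PI 2), Il4 (−6.53 ± 0.47), Il17a (−5.75 ± 0.88, or −5.10) and Il17f (−5.27 ± 0.68) were among the largest falls, with the receptor Cd160 (−5.05 ± 0.34). Ccl1 had no count in any CsA-stimulated library and was at least 530-fold lower (314-fold without CsA_PI 2), and Il3 at least 101-fold lower (59.7-fold without CsA_PI 2). The firmest rises were those of S1pr1 (3.67 ± 0.22), to 317.5, 481 and 314 CPM, and of Il16, a secreted CD4 ligand (3.47 ± 0.21). Fanci (3.68 ± 0.42) and Neurl3 (3.42 ± 0.33) rose as well. Tbxa2r (4.09, or 1.80 without CsA_PI 2), Tmie (3.40, or 1.29), Tdrp (3.85, or 2.60) and Ighg1 (3.66; adjusted p = 0.0661 without CsA_PI 2) owed part of their rise, or their call, to that library.

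By list, 15 of 20 cytokines fell and none of them rose (median −4.33, camera adjusted p = 3.19e-13), as did 4 of 6 chemokines. Without CsA_PI 2, 16 of 21 cytokines fell (median −3.76, or −3.61 with bounded folds). Chemokines then counted 4 lower and 1 higher of 6. TNF-family ligands counted 6 lower and 1 higher of 8, with Tnfsf14 at −4.90 and Cd40lg at −4.62. All 24 ribosome biogenesis genes fell (median −2.07, camera adjusted p = 8.01e-35), among them Polr1b (−2.98) and Rrp12 (−2.72). All 24 also fell without CsA_PI 2 (median −1.81). Heat shock genes counted 10 lower of 12 (8 without CsA_PI 2), with Hspd1 at −1.98. Glycolysis counted 7 lower of 18 (8 without CsA_PI 2), with Hk2 at −2.95. Amino acid transport counted 7 lower and 1 higher of 15, with and without CsA_PI 2, and Slc7a5 was at −2.73. Inhibitory receptors counted 8 lower and 1 higher of 19, or 12 lower adjusted over the list alone, with Btla at −3.30 and Ctla4 at −1.85. Quiescence and homing genes counted 10 higher and 1 lower of 20 (median 0.76, or 0.48 without CsA_PI 2), with Tcf7, a factor of naive cells, at 2.65 and Cxcr4 at 2.90; without CsA_PI 2 they counted 8 higher and 3 lower. The AP-1 family counted 3 lower of 12, or 5 adjusted over the list alone (Mafk at −1.81, Mafg at −1.10); Junb was uncalled at −0.57 (adjusted p = 0.211). Other immediate-early genes counted 10 lower of 24, with Spry1 at −4.88, Plk3 at −3.67 and Nr4a2 at −3.64. Without CsA_PI 2 they counted 12 lower and 2 higher. NF-kB pathway genes counted 10 lower and 3 higher of 21, with Nfkbid at −2.91, or 9 lower and 5 higher without CsA_PI 2. Surface activation markers counted 6 lower and 1 higher of 12 (Slamf1 at −4.44), or 6 lower and 4 higher without CsA_PI 2.

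Among the remaining lists, interferon-stimulated genes counted 6 higher and 1 lower of 15, with the antiviral genes Ifit3 at 2.70 and Ifit1 at 1.96 (camera adjusted p = 0.0511, or 0.00368 without CsA_PI 2). Their adjusted p was 0.123 with an estimated correlation, and 0.0545 without CsA_PI 2. By fry it was 0.0016, and 3.16e-05 without CsA_PI 2. T cell identity genes counted 7 lower of 14, with the adaptor Lcp2 at −2.69 and the kinase Zap70 at −1.86. The calcineurin-NFAT list split, 4 higher and 4 lower of 20, with Rcan3 at 2.36 and Nfatc3 at 1.73 beside the falls of Nfatc1 and Rcan1 (adjusted p = 0.967). T helper factors counted 6 lower and 2 higher of 18, with Tbx21 at −3.30 and Bcl6, a factor of follicular helper cells, at 1.74 (adjusted p = 0.0976). Cyclophilins, to which CsA binds, counted 2 lower of 7 (adjusted p = 0.0392, or adjusted p = 0.283 with an estimated correlation), with Ppif at −1.79, regulatory T cell markers 3 lower of 10 and housekeeping genes 1 lower of 12.

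For this comparison 3318 genes were called, 1485 higher and 1833 lower, and 3393 without CsA_PI 2; 2709 genes were called in both fits. Camera called 16 lists, and 7 held with an estimated correlation (cytokines, TNF-family ligands, inhibitory receptors, quiescence, ribosome biogenesis, glycolysis and amino acid transport). Adjusted p was 0.0978 with an estimated correlation for chemokines, 0.123 for immediate-early and heat shock genes, 0.274 for T cell identity, 0.107 for regulatory T cells and 0.283 for AP-1, NF-kB and activation markers. For each of these lists the adjusted p by fry was at most 0.0101. Without CsA_PI 2, the estimated correlation left calls for cytokines (0.00163), TNF-family ligands (0.00237), ribosome biogenesis (0.00604) and immediate-early genes (0.0424). Inhibitory receptors (0.0967), quiescence (0.0928), glycolysis (0.0791) and amino acid transport (0.0545) then had none. Library totals moved the median of all genes by 0.34 and the split of calls to 2870 higher and 1193 lower, under which the housekeeping list went to 3 higher and 0 lower.

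Genes induced in vehicle were then sorted by their response to CsA. Of 2065 genes induced at least 2-fold, 1310 (63.4%) were lower with CsA, 0 were higher and 755 (36.6%) had no call. Without CsA_PI 2, 1145 of 2078 (55.1%) were lower, 43 higher and 890 (42.8%) uncalled. A lower level with CsA need not be a smaller induction. The interaction was called, in either direction, for 766 of the 2065, and for 845 of the 2078 without CsA_PI 2. Genes still called higher on stimulation under CsA, by whatever amount, numbered 400 of 2065 (19.4%), or 1141 of 2078 (54.9%) without that library. With CsA_PI 2 kept, this number rested on single libraries. All calls for stimulation with CsA then numbered 0 to 6 without ethanol_US 1, any CsA_US library, any ethanol_PI library, CsA_PI 1 or CsA_PI 3. They numbered 268 without ethanol_US 3. The ethanol libraries belong to neither group of that comparison but enter the shared spread. The common coefficient of variation of that spread was 0.349 with CsA_PI 2 and 0.301 without it. The most induced genes with no call for CsA and none in the interaction were Fosl1 (−1.26 ± 0.84), Mir155hg, the precursor of miR-155 (−1.57 ± 0.84), Prag1 (−1.34 ± 0.67), Nr4a1, Atf3 (−1.79 ± 0.62) and Gzmb, the cytotoxic protease granzyme B (−0.16 ± 0.79). Without CsA_PI 2, Mir155hg (adjusted p = 0.00878), Nr4a1 and Atf3 (adjusted p = 0.0226) were called lower, and Gzmb stood at 0.43 (adjusted p = 0.474). The median log2 change on stimulation over the induced genes was 1.78 in vehicle and 0.64 with CsA, and the median ratio of both changes was 0.351 (0.462 without CsA_PI 2). For CsA_PI 1, 2 and 3 in turn, each set against the mean of all CsA_US libraries, the ratio was 0.446, 0.063 and 0.465. Independent calls would share 262.9 genes between induction and a fall with CsA. Simulated libraries with the stimulation observed in vehicle and no CsA effect had 2091 to 2215 induced genes in 10 runs; CsA had 0 calls in them, so no overlap could arise and only their covariance serves as a baseline. That covariance between both fold changes, which share the vehicle-stimulated group, was −0.19 to −0.165, against −1.25 observed and −1.01 without CsA_PI 2. Across genes, which are not independent replicates, the stimulation effects with and without CsA correlated at r = 0.544 (0.552 without CsA_PI 2). By their labels these effects share no library. Simulations with no effect gave 0.003, a value set by their design, so they offer no test of this correlation.

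**Figure D2:**
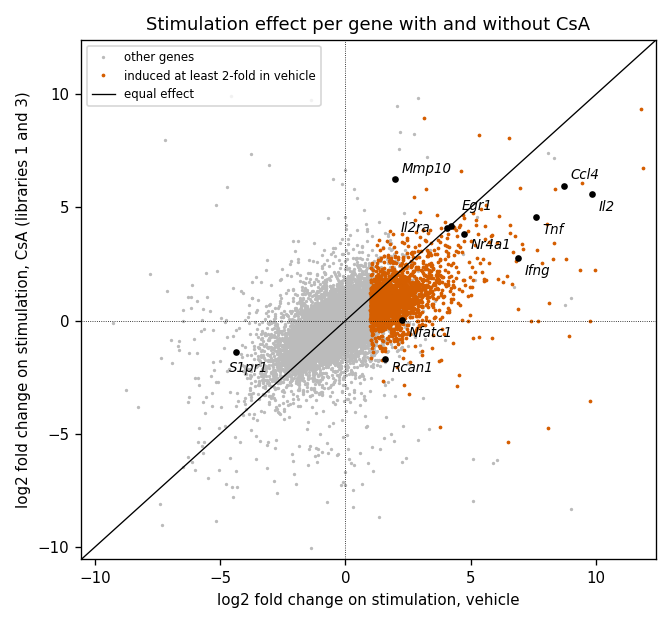
Log2 fold change on stimulation of each gene in vehicle (horizontal) and with CsA from libraries 1 and 3 (vertical), orange where induced at least 2-fold in vehicle. Il2 and Tnf lie below the line of equal effect, Egr1 (4.23 and 4.17) and Il2ra (4.06 and 4.08) lie on it, and Nfatc1 lies at 0.02 on the vertical axis.

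CsA in unstimulated cells asked what the drug did by itself. Gbp11, an interferon-inducible GTPase, was the only gene called with all 12 libraries, lower by −2.46 ± 0.27 (n = 3; edgeR adjusted p = 0.011). It was at 14.4, 11.9 and 15.3 CPM in vehicle and at 2.78, 1.66 and 3.07 CPM with CsA. Egr2 stood at −3.01 ± 0.51 (adjusted p = 0.404), with 79.7, 43.8 and 32.1 CPM in vehicle and 6.69, 7.89 and 4.65 CPM with CsA. Without CsA_PI 2, which belongs to neither group but enters the shared spread, Egr2 was called lower (SE 0.33; adjusted p = 0.00771). In that fit Gbp2 (−1.13 ± 0.16), Nr4a2 (−1.05 ± 0.15), the chaperone Hspa4l (−1.48 ± 0.18), Gm12250 (−1.28 ± 0.15) and Gbp11 fell too, and Amy2a5 (8.11 ± 0.99) rose; all of these but Gbp11 and Egr2 were chosen after their values were seen. Nfatc1 (−0.03 ± 0.16), Nr4a1 (−0.09 ± 0.66) and Cd69 (−0.49 ± 0.47) had no call.

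No list had a called member in this comparison with all 12 libraries. Camera called inhibitory receptors lower (median −0.15; adjusted p = 0.00209, or 0.315 with an estimated correlation), interferon-stimulated genes lower (median −0.26; 0.00914, or 0.173), TNF-family ligands lower (0.0182, or 0.568), immediate-early genes lower (0.0182, or 0.724) and amino acid transport higher (median 0.12; 0.0142, or 0.552). By fry no list was called, the lowest adjusted p being 0.135 for interferon-stimulated genes. The cytokine list had a camera adjusted p of 0.0551, and 0.0498 with the replicate number as a block. Adjusted over the list alone, 2 cytokines, 3 immediate-early genes, 2 inhibitory receptors and 1 activation marker were lower. The call count of 1 compares with 465 genes at an unadjusted p under 0.05 and 20 genes by DESeq2. Those 465 are a share under 0.05 of the 14398 genes tested, so no more than chance alone would give. Leaving out ethanol_US 1 or 3, or CsA_US 2 or 3, gave 0 calls, CsA_US 1 gave 2 and CsA_PI 2 gave 7. A fit of only the groups compared gave 1 higher and 0 lower, so Gbp11 was not called in it. In simulated data, 51.5% of genes changed by 2 on the log2 scale and 10.4% of genes changed by 1 were recovered.

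Stimulation of CsA-treated cells asked what PMA and ionomycin still changed in the presence of CsA. Egr1 rose by 3.65 ± 0.79 (n = 3; edgeR adjusted p = 0.0423), or by 4.17 ± 0.20 without CsA_PI 2, to 1063 and 1202 CPM in CsA_PI 1 and 3 from a mean of 61.9 CPM. Il2ra rose by 3.57 ± 0.80 (adjusted p = 0.043; 4.08 ± 0.24 without CsA_PI 2), Myc by 3.69 ± 0.63 and Egr2 by 4.29 ± 0.54 (adjusted p = 0.0184). Il2 rose by 5.07 ± 0.78 (adjusted p = 0.0395) to 25.4 and 23.3 CPM in those libraries, from a mean of 0.506 CPM. Nfatc1 (0.06 ± 0.16; adjusted p = 0.85) and Nfkbia (−0.04 ± 0.22; adjusted p = 0.936) had no call. The largest rises by the naming rule were those of Il17a, from a mean of 0.0206 CPM to 4.68, 0.0682 and 1.47 CPM, of Mmp10, a matrix metalloproteinase (5.70 ± 1.16, to 293, 7.71 and 576 CPM), and of Ccl4 (5.41 ± 1.03). The largest falls were those of Klf2, a quiescence factor (−2.65 ± 0.66, or −4.01 without CsA_PI 2), Frat2 (−2.44 ± 0.58, or −3.25) and Fbxl22 (−2.16 ± 0.42, or −2.76).

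By list, 9 of 20 cytokines rose with all libraries and 14 of 21 without CsA_PI 2. The AP-1 family counted 5 and 10 higher of 12, other immediate-early genes 9 and 19 of 24, NF-kB genes 9 and 15 of 21, activation markers 8 and 10 of 12 and ribosome biogenesis 11 and 17 of 24. Interferon-stimulated genes counted 2 and 5 higher of 15. Quiescence genes counted 2 lower of 20, and 10 lower with 4 higher without CsA_PI 2. No list held with an estimated correlation with all libraries, the lowest adjusted p being 0.106 for interferon-stimulated genes and that of cytokines 0.13 with an estimated correlation. By fry the adjusted p was 0.0036 for interferon-stimulated genes, 0.019 for cytokines, and 0.0697 for both chemokines and the AP-1 family. Without CsA_PI 2, cytokines, immediate-early genes and activation markers reached 0.00107 with an estimated correlation.

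This comparison had 760 calls, 561 higher and 199 lower, with 3702 genes at an unadjusted p under 0.05 and 2022 calls by DESeq2. Its count rested on single libraries. Without CsA_PI 2, 4321 genes were called (2125 higher, 2196 lower), which included all 760. With CsA_PI 2 kept, leaving out any other library but ethanol_US 2 gave between 0 and 268. This held for ethanol libraries too, which belong to neither group but enter the shared spread. Library totals moved the median of all genes by −0.24 and left 5 calls. Without CsA_PI 2 they gave 1211 higher and 3695 lower, and the amino acid list turned from a median of 0.11 to −0.24.

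**Figure D3:**
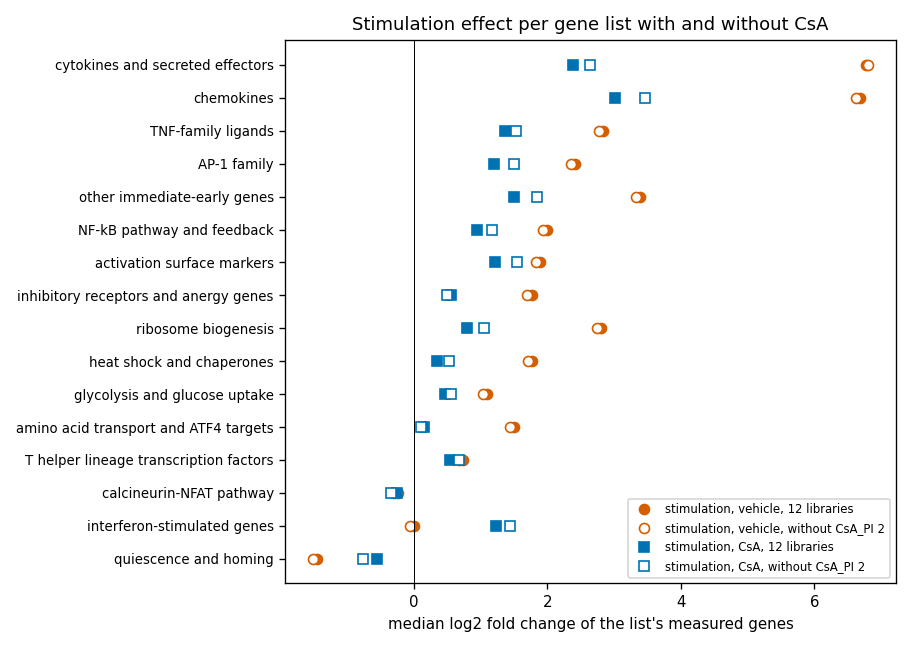
Median log2 fold change on stimulation over the measured genes of 16 lists, in vehicle (circles) and with CsA (squares), filled with all 12 libraries and open without CsA_PI 2. Cytokines stood at 6.78 in vehicle and 2.38 with CsA, and interferon-stimulated genes at 0.00 and 1.22. With library totals the amino acid list with CsA turned from 0.15 to −0.11.

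The interaction tested whether stimulation acted differently under CsA than in vehicle. Il2 responded less under CsA, by −4.84 ± 1.11 (n = 3; edgeR adjusted p = 0.0208), as did Ifng (−4.63 ± 0.76; adjusted p = 0.00373), Tnf (−3.60 ± 1.00; adjusted p = 0.0468) and Csf2 (−5.08 ± 1.29). Nfatc1 (−2.27 ± 0.23; adjusted p = 0.000228) and Nfkbia (−2.17 ± 0.31; adjusted p = 0.00131) also responded less. No difference was called for Egr1 (−0.64 ± 1.01), Egr2 (−0.44 ± 0.67), Il2ra (−0.54 ± 1.03), Fos (−1.03 ± 0.58), Jun (−0.45 ± 0.33) and Nr4a1 (−1.44 ± 0.94). Without CsA_PI 2 the values of Egr1, Egr2 and Il2ra were −0.06 ± 0.26, −0.02 ± 0.50 and 0.03 ± 0.30. Myc (−1.95 ± 0.81), Cd69 (−1.58 ± 0.67) and Rcan1 (−2.20 ± 0.69) were called without CsA_PI 2, at −1.41 (adjusted p = 0.0125), −1.08 (adjusted p = 0.0069) and −3.24 (adjusted p = 0.000513), and Rcan1 also with the replicate number as a block (−2.42).

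The largest reductions by the naming rule also took in Ccl1, Frat2 (−5.05 ± 0.80, or −5.79 without CsA_PI 2), Cd160 (−4.90 ± 0.44), Il17f (−4.74 ± 1.01) and Il4 (−4.55 ± 0.59). Large positive values included those of Fanci (4.18 ± 0.55), Tdrp (3.71 ± 0.90, or 2.45 without CsA_PI 2), Pakap (3.67 ± 0.91), Card6 (3.46 ± 0.64, or 2.56), Il16 (3.30 ± 0.28), 9930111J21Rik1 (3.25 ± 0.60) and S1pr1 (3.22 ± 0.28). All 24 ribosome biogenesis genes responded less (camera adjusted p = 5.17e-33, or 0.043 with an estimated correlation). TNF-family ligands counted 6 lower and 1 higher of 8 (3.11e-10, or adjusted p = 0.043 with an estimated correlation) and amino acid transport 5 lower of 15 (3.49e-07, or 0.0473). Cytokines counted 8 lower of 20 (3.71e-10, or adjusted p = 0.0608 with an estimated correlation) and glycolysis 5 lower of 18 (0.000236, or 0.0583). Interferon-stimulated genes counted 3 higher of 15 (0.00244, or 0.0551). By fry the adjusted p was 0.00168 for cytokines, 0.000413 for glycolysis and 0.00088 for interferon-stimulated genes. Without CsA_PI 2, 6 interferon-stimulated genes were higher. Without that library cytokines counted 10 lower of 21, and the adjusted p with an estimated correlation was 0.00437 for them, 0.0126 for interferon-stimulated genes and 0.102 for glycolysis. In all, 1400 genes were called, 509 higher and 891 lower, and 1865 without CsA_PI 2. Counts fell to 787 without ethanol_US 1, 795 without CsA_US 3 or ethanol_PI 1 and 886 without ethanol_PI 3. Library totals moved the median of all genes by 0.36 and the split to 950 higher and 531 lower.

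Transcripts were tested for genes known for alternative promoters. In stimulated cells CsA lowered 4 of 24 transcripts. Nfatc1-201 fell by 2.31 ± 0.16 on the log2 scale (n = 3; edgeR adjusted p = 7.97e-07), from 474, 439 and 466 to 85.9, 88.0 and 105 CPM. Nfatc1-202 (−2.24 ± 0.18), Nfatc1-204 (−1.85 ± 0.51; adjusted p = 0.025) and Rcan1-201 (−3.20 ± 0.70; adjusted p = 0.00732) fell as well. Nfatc1-201 and Nfatc1-202 rose on stimulation in vehicle, by 2.39 ± 0.16 and 2.42 ± 0.18, and both were called in the interaction. Without CsA_PI 2, 6 transcripts were called, Crem-233 (0.52 ± 0.13, higher) and Rcan1-202 being the others. The deposited tables carry no measure of how surely reads were assigned among transcripts of a gene.

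Markers of other spleen cells differed by replicate number. Cd79a, part of the B cell receptor, was at 225, 258.5, 76.1 and 229.8 CPM in the libraries numbered 2 of the vehicle unstimulated, CsA unstimulated, vehicle stimulated and CsA stimulated groups, and at 20.7 to 38.2 CPM in the other 8. Lyz2, the lysozyme of myeloid cells, was at 96.8 to 119 CPM in those numbered 2 and at 10.5 to 32.8 CPM in the others. In none of the 5 comparisons was a B cell marker called with all 12 libraries. Summed over 12 B cell markers the libraries held 2311 to 4862 CPM. For 18 myeloid and dendritic markers the sums were 611 to 6233 CPM. The fit without CsA_PI 2 keeps the marker-rich libraries numbered 2 of the other groups, so it does not balance these markers. In it the B cell median was −1.28 with CsA in stimulated cells, −1.825 on stimulation with CsA and −1.135 in the interaction. Myeloid and dendritic medians were −0.75, −0.89 and −0.95, and neither list had a camera call in these comparisons. Camera called neither list, nor CD8 and NK, erythroid and platelet, or mitochondrial lists, in any comparison with all 12 libraries. CD8 and NK markers counted 2 higher and 2 lower of 10 on stimulation in vehicle and 2 higher and 1 lower with CsA in stimulated cells. Median, mean and test direction differed in sign, in lists that camera did not call, as follows. In vehicle they did for calcineurin-NFAT (median −0.24, mean 0.06), myeloid, erythroid and interferon-stimulated lists, and with CsA in stimulated cells for CD8 and NK (−0.06, 0.08) and housekeeping lists (0.04, −0.01). They also did for T cell identity, myeloid, erythroid and mitochondrial lists with CsA in unstimulated cells, for cyclophilins and B cell markers on stimulation with CsA, and for CD8 and NK and housekeeping lists in the interaction. A single myeloid and a single erythroid marker rose in vehicle, and mitochondrial transcripts had 0 calls of 12. Features that resemble ribosomal RNA took 10.2%, 9.97% and 5.43% of counts in CsA stimulated and 3.73%, 3.77% and 2.78% in vehicle stimulated libraries, and 2.58% to 11.8% in unstimulated ones. Mitochondrial transcripts took 1.64% to 2.72%.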

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

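The tests on the library labelled CsA_PI 2 and on B cell and myeloid markers were chosen after the result was seen; the splits of the samples were planned.

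Stimulation acted differently under CsA than in vehicle for 1400 genes by the test of that difference, and 17 genes were called in opposite directions in the vehicle and CsA arms (125 without CsA_PI 2). A gene of this kind needs a call for stimulation with CsA. With CsA_PI 2 kept, those calls numbered 0 to 6 without ethanol_US 1, any CsA_US or ethanol_PI library, CsA_PI 1 or CsA_PI 3. They numbered 268 without ethanol_US 3 and 0 in a fit of only the groups compared. Without CsA_PI 2 they numbered 4321. Frat2, an activator of Wnt signalling, was at 2.60 in vehicle and −2.44 with CsA (interaction −5.05; −3.25 and −5.79 without CsA_PI 2), and Rnf128, the anergy-related ubiquitin ligase, at 0.82 in vehicle and called lower with CsA (interaction −1.82). Of 60 splits of the samples for the interaction, the real one included, 5 gave at least its 1400 genes (highest other 1714). All 5 were among the 8 splits that kept both stimulated groups whole. Such splits keep the difference between CsA-stimulated and vehicle-stimulated cells (3318 calls), so this count cannot decide on chance. Splits that broke these groups gave at most 1 gene.

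The other comparisons had 10 splits each, too few for a share under 0.05. Stimulation in vehicle gave 5728 genes in the real split and 0 in the highest other, so 1 split of 10 reached it; CsA in stimulated cells gave 3318 and 0, also 1 split, and stimulation with CsA 760 and 0, also 1 split. CsA in unstimulated cells gave 1 gene, reached by 3 splits (highest other 1). By replicate number, the real split parts all 3 numbers; the splits with 1 gene part a single number, and the other splits that part all 3 gave 0.

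The library labelled CsA_PI 2 lacked the stimulation response (induced-gene score 4.23, against 5.06 and 5.09 in CsA_PI 1 and 3). Cells given CsA and left unstimulated, or fully blocked, were argued against: 6 of the 6 genes lower with CsA in unstimulated cells lay above every CsA_US library, among them Egr2 (44.6 against at most 7.89 CPM). All of them but Hspa4l also lay above in CsA_PI 1 and 3 (Egr2 at 122.6 and 210.6 CPM). The count therefore does not test cells weakly stimulated under CsA. An exchange with another of the 12 libraries was argued against, since 0 unstimulated libraries scored above 4.6. A second library from the vehicle unstimulated sample numbered 2 may be the source: chi-square per gene against it was 4.15, and the lowest among pairs without this library was 15.02. Its next closest library, CsA_US 2, was at 71.4. These values argue against a sample unrelated to the vehicle unstimulated sample numbered 2. How the library came to carry its label, by a single wrong label or a swap outside this series, stays open.

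B cell and myeloid markers were highest in the libraries numbered 2, with Cd79a at 76.1 to 258.5 CPM there and at most 38.2 CPM elsewhere. Over the whole lists, 86.7% of these markers were highest in number 2 in all 3 groups tested, against 8.2% of all genes, which extends the pattern but does not test its source. Residual B and myeloid cells in the preparation numbered 2, which purification was meant to remove, are a candidate explanation that stays open. No biological explanation was tested, since the labels do not say what the replicate numbers share.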

How the results depend on the processing

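Tests without CsA_PI 2 combined with another choice, and those without replicate 2, were chosen after the result was seen; the cause of a moved count was not tested. For CsA in unstimulated cells (1 gene, lower), DESeq2 gave 20 and a fit of only the groups compared 1 higher and 0 lower; without CsA_PI 2, the replicate block gave 15, DESeq2 48, RLE 7 and library totals 9; leaving out libraries gave 0 to 7. For stimulation with CsA (760), library totals gave 5, DESeq2 2022, the replicate block 441 and a fit of only the groups compared 0; without CsA_PI 2, the block gave 4831, DESeq2 4834, RLE 4318 and totals 4906; leaving out libraries gave 0 to 4437. In that comparison the correlations of equally numbered libraries were 0.033, 0.11 and 0.123, not all above 0.1, so the numbers were not read as pairs there; 12 of 12 libraries correlated best with one of their own number, a hint from the data, not the design. With the block, Egr1, Klf2 and Frat2 had no call in it. For the interaction (1400), DESeq2 gave 2120, and without CsA_PI 2 the block gave 2274 and DESeq2 2485; leaving out libraries gave 787 to 1865. Induced genes lower with CsA (1310, 63.4% of the induced) numbered 579 (67.6%) at 4-fold induction and 734 (68.0%) with library totals, or 702 (61.4%) without CsA_PI 2, since fewer genes were then induced. Of 16 lists called for CsA in stimulated cells, 7 held with an estimated correlation, and 4 of these lost it without CsA_PI 2 (0.0545 to 0.0967). With library totals Dusp1 and Dnaja1 turned to −0.56 and −0.47 on stimulation in vehicle, with all libraries and without CsA_PI 2, and Phgdh to −0.35 without it; Gzmb with CsA in stimulated cells turned to 0.60 without replicate 2, and ranged from −0.71 to 0.60 over libraries left out. Calls for stimulation in vehicle ranged from 4511 to 7845 and for CsA in stimulated cells from 2233 to 4063 over all settings. The replicate block changed no call printed in the report for paired comparisons beyond those given beside it. Depth limits what a count of 0 shows to 0.162 to 0.285 CPM.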

Other observations

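The tests on interferon gamma, and on cell markers without all libraries numbered 2, were chosen after the result was seen; the other tests on genes higher than in both other groups were planned once that pattern was defined and before their values were seen.

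Some genes were higher in CsA-stimulated cells than in both vehicle-stimulated and CsA-unstimulated cells, 44 with all libraries and 376 without CsA_PI 2, where 300 were lower than in both. Both comparisons share the CsA-stimulated libraries, so a deviation of these libraries moves both fold changes the same way. The overlap to be found without an effect was not simulated. Without that library Mmp10 was higher by 4.39 than in vehicle-stimulated and by 6.25 than in CsA-unstimulated cells. Neurl3, a ubiquitin ligase, was higher by 3.77 and 1.34, Ifit3 by 3.13 and 2.10, the ubiquitin-like Isg15 by 1.97 and 2.06, the costimulatory receptor Cd28 by 1.93 and 1.56 and the adhesion receptor Cd44 by 0.80 and 2.65. Of the 376, 96 rose on stimulation in vehicle, 64 fell and 216 had no call. Activation markers held 4 of 12 (0.30 expected, Fisher adjusted p = 0.00404) and interferon-stimulated genes 4 of 15 (0.37 expected, Fisher adjusted p = 0.00525). Fisher's exact test treats genes as independent, which genes regulated together are not, so these p-values are too small to rely on.

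Of these 376 genes, 67.0% kept both calls with library totals. Those totals moved the median of all genes by −0.35 for stimulation with CsA and by 0.17 for CsA in stimulated cells. Scaling to a changed RNA composition was thus argued against as the whole cause only for the rise over CsA-unstimulated cells. Both scalings are relative, so a change in total RNA was not tested. A GC trend was argued against too, since 96.3% kept both calls after it was removed. RNA of B, myeloid or dendritic cells was tested by the median of 30 of their markers in CsA-stimulated against vehicle-stimulated cells. Without CsA_PI 2 alone it was −1.23, a value lowered by the marker-rich vehicle library numbered 2, and without all libraries numbered 2 it was 0.03, which argues against this source. An effect of CsA on these genes in stimulated cells may remain as a hypothesis, found and tested on the same libraries; calcineurin activity was not measured, so no table parts it from other effects of the drug, and the 300 genes lower than in both were not weighed.

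Interferon-stimulated genes had a median of 0.62 with CsA in stimulated cells without CsA_PI 2, while Ifng fell by 4.49 on the log2 scale. A higher Ifng transcript was thus not there to account for the higher median. The list was called by camera (adjusted p = 0.00368) and fry (adjusted p = 3.16e-05), but not by camera with an estimated correlation (adjusted p = 0.0545). The protein was not measured, so the role of interferon gamma stays open.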
